A study of Solanum lycopersicum with 4 samples.

How the data were processed

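The data are 4 single-colour Affymetrix tomato arrays hybridised with biotin-labelled RNA from whole seedlings, 2 of wild type and 2 of the L7 line. Genotype and replicate number came from the sample titles. The labels do not say that replicates came from separate cultures, so the spread between samples of a genotype may be technical. The p-values draw on that spread and, for the most part, on the spread of other probe sets. Per the labels, GCOS, the Affymetrix operating software, produced the deposited intensity values, 1 per probe set on a linear scale. Its version, background correction and scaling target are not given in the sources used here. The deposited values themselves have the same mean, 500.1, on every array once the lowest and highest 2% of probe sets are left out. No detection calls were used. No 2 arrays held identical values.

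Signals were floored at 1 and converted to log2 with no further normalization between arrays. The 108 control probe sets were left out, as was the dimmest 25% of the others by mean log2 signal over the 4 arrays, which left 7576. A linear model with genotype as its term was fitted with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a trend of variance on signal, two-sided tests and Benjamini-Hochberg adjustment over the probe sets. Adjusted p-values, SEs and 95% intervals come from this model. It has 2 residual degrees of freedom per probe set and borrows 20.1 from the others. An SE or p-value thus reflects the spread of probe sets of similar signal more than that of the gene's own arrays. Differences are L7 minus wild type.

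The annotation table gives 1 symbol for 909 probe sets and none for 9192. These 909 stand for 803 genes, and 885 matched the RefSeq gene table, which was used for synonyms. A gene was represented by its brightest probe set, giving 658 tested genes, 42 of them with more than 1 tested probe set. No probe set was annotated as an inositol polyphosphate 5-phosphatase, so transgene expression was not measured.

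Gene lists were tested with camera at a preset correlation of 0.01 where at least 5 genes were tested, with an estimated correlation and fry beside it. Camera compares a list with the other named genes, whereas fry asks whether its genes move one way on balance. There were 2 families of list tests, each adjusted on its own. The first held 24 lists given by text patterns fixed before the data were examined, and 4 could be tested. The second held 21 lists filled by hand from the array's symbols, and 20 could be tested. It was added because most patterns found no gene, and after a first fit had shown its top probe sets, among which the cathepsin D inhibitor was recognised. Most subjects were those of the first family, with AP2/ERF transcription factors as a new one.

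Genes were named by a rule fixed before the data were examined: up to 12 called genes with the largest rise and 12 with the largest fall, with both arrays of 1 genotype on the same side of both arrays of the other and the higher mean at or above the median, and the 4 genes of lowest p in each list. ARG2, LAPA1 and the called probe set of ACO6 fall outside it and were chosen after their values were seen.

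Alternatives fixed beforehand were quantile normalization, median centring, no filter or a 50% filter on dim probe sets, an added constant of 16, the replicate number as a block, other variance models, each array left out in turn, other list tests and the mean of a gene's probe sets. A block on the level of the hybridisation controls and a background of all probe sets for the lists were chosen after seeing the data. The procedure was tested on simulated data with 200 changed probe sets among 7576. It made 36 calls, 2 of them false, and recovered 8% of changes of log2 1 and 26% of changes of log2 2, and 84.6% of the latter among 26 bright probe sets. With no changes simulated, it made 0 calls. The simulated variance was a function of signal alone, as the trend assumes, and probe sets were drawn independently. These counts therefore do not test the reliance on the trend.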

Results

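Transcript levels were measured on Affymetrix tomato arrays in whole seedlings of cultivar Micro-Tom, either wild type or L7, a transgenic line carrying an inositol polyphosphate 5-phosphatase (InsP 5-ptase), an enzyme that removes a phosphate from inositol phosphate messengers. Each genotype had 2 arrays. All seedlings were 17 days old. They had spent 10 days under 12 h light and 12 h dark, then their last 7 days in continuous light at 50 umol per square metre per second. Both genotypes thus had the same light history, and no array shows either genotype without that continuous light. The median signal over 10101 probe sets was 216 and 188 in wild type and 199 and 215 in L7. Log2 signals of the 7576 tested probe sets correlated across probe sets at r = 0.75 between the wild-type arrays and 0.77 between the L7 arrays, while the highest correlation of any pair, 0.79, joined wild type replicate 2 and L7 replicate 1. The number of arrays limits the precision of every value given here. The ratio of 3' to 5' signal of the actin control, a measure of RNA integrity, was 3.34 and 4.69 in wild type. In L7 it was 2.80 and 2.48, without overlap. That of the GAPDH control was 2.60 and 2.77 against 2.23 and 2.60. The ratio of 3' to middle signal of the EF1a control was 1.84 and 2.57 in wild type and 2.16 and 1.72 in L7.

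The comparison of L7 with wild type asks which transcripts differ in the transgenic line under continuous light. Proteinase inhibitor and pathogenesis-related genes formed the largest named group that was higher in L7. LOC543954, listed with the synonym PIIF, rose 17.3-fold (95% interval 14.1 to 21.2, n = 2 arrays per genotype), with signals of 2392 and 2037 in wild type and 38377 and 37816 in L7 (limma adjusted p = 4.15e-15). PR1b1, a pathogenesis-related protein of the PR-1 family, rose 9.70-fold (7.60 to 12.4, limma adjusted p = 5.00e-12). Among the genes that fell, LOC543809, listed as INS-1P and known as a myo-inositol-1-phosphate synthase, dropped to 0.392 times its wild-type signal (0.302 to 0.510, limma adjusted p = 0.000101).

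In all, 86 of the 7576 probe sets passed limma's test at an adjusted p below 0.05, of which 50 were higher and 36 lower in L7, and 53 of them differed more than 2-fold. An unadjusted limma p below 0.05 was reached by 551 probe sets, against 378.8 expected if p-values were uniform without any difference. Whether this model gives uniform p-values could not be checked with these arrays. The count rests on the trend of variance with signal: without that trend limma called 0 probe sets, with 404 at an unadjusted p below 0.05. A fit that leaves out 1 array takes its spread from the other genotype alone. A call lost there need not mean that the difference rests on the array left out. The chitinase CHI9 had a log2 difference of 1.06 over all arrays, 1.06 without L7 replicate 1 and 1.05 without L7 replicate 2. That of LOC544298 moved from -0.92 to -0.55 without L7 replicate 2. The array annotation names 27 of the called probe sets, each a different gene, with 21 higher and 6 lower, and the other 59 are unnamed here.

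**Figure D1:**
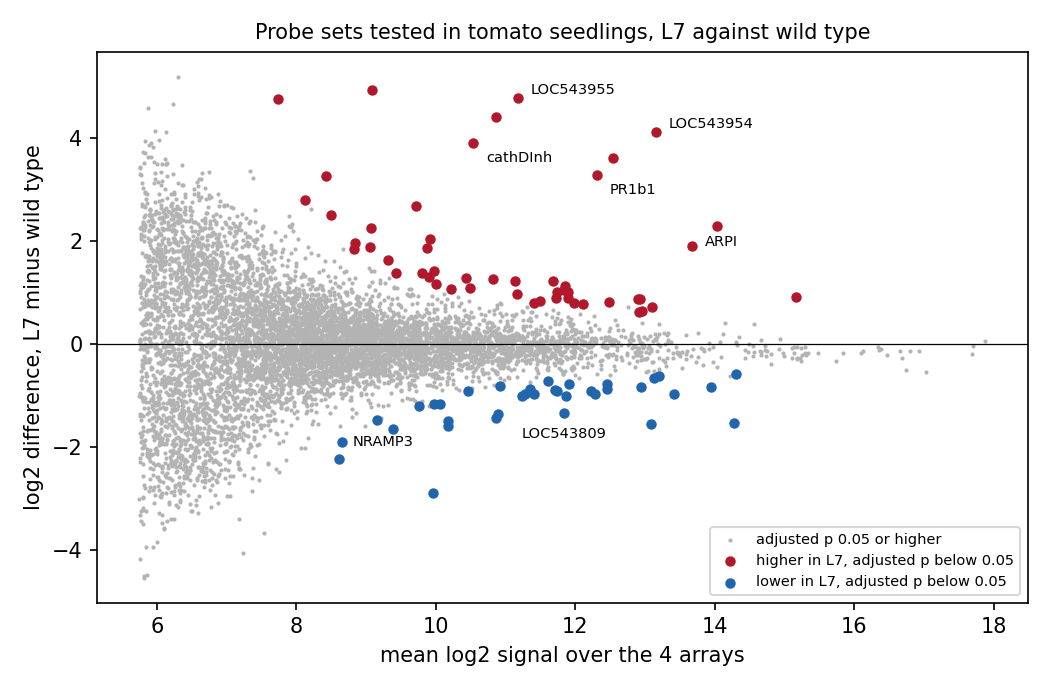
Each point is 1 of the 7576 tested probe sets, with its mean log2 signal over the 4 arrays on the horizontal axis and the log2 difference of L7 minus wild type on the vertical axis. The 50 red points and 36 blue points passed an adjusted p of 0.05, and grey points of low signal spread as far from 0 as the called genes do.

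Of 9 tested genes listed as proteinase inhibitors or wound responsive, 4 rose, 0 fell and 5 did not pass the test, and 6 passed when adjusted over the list alone. Besides LOC543954, the called genes were cathDInh, whose symbol names a cathepsin D inhibitor (log2 difference 3.91 ± 0.27 SE, adjusted p = 1.11e-09), TD2, a threonine deaminase that responds to wounding (2.80 ± 0.63 SE, adjusted p = 0.0217), and ARPI (1.90 ± 0.19 SE, adjusted p = 9.75e-07). The other genes that passed over the list alone, named after their values were seen, were ARG2, an arginase (log2 1.09, adjusted p = 0.167 over all probe sets), and LAPA1, a leucine aminopeptidase (adjusted p = 0.208). The signals of LAPA1 were 16.2 and 10.6 in wild type and 362 and 638 in L7, and at so low a wild-type level its log2 difference depends on the scale, being 5.20 as deposited and 4.09 after adding 16 to each signal. The list had a median log2 difference of 1.90 and shifted upward against the other named genes (camera adjusted p = 2.96e-15). The shift had an adjusted p = 0.145 with an estimated correlation and an adjusted p = 0.109 in fry. TD2 lost its call without either L7 array and with the dimmest 50% left out (adjusted p = 0.0505), and ARPI lost its call without L7 replicate 1. The log2 difference of TD2 was 2.07 without wild type replicate 1 and 3.53 without wild type replicate 2. The SE of ARPI draws mostly on other probe sets, while its own SD was log2 0.50 within wild type and 0.43 within L7. With a robust trend, the limma adjusted p of ARPI was 0.0260. LOC543955 stands outside the lists and had the largest rise among the called named genes, 27.5-fold (20.4 to 36.9, limma adjusted p = 1.40e-13), but a second probe set for it gave a log2 difference of 0.32 (limma adjusted p = 0.844).

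All 12 tested pathogenesis-related and defence genes had a higher mean in L7, and 7 of them rose, 0 fell and 5 did not pass, with 8 passing when adjusted over the list alone. Beside PR1b1, they were PR-5, a thaumatin-like protein (log2 3.27 ± 0.61 SE), GluB, a basic beta-glucanase (2.69 ± 0.32 SE), P4, another PR-1 protein (1.38 ± 0.32 SE), NP24-I, an osmotin-like protein (1.30 ± 0.28 SE), and the chitinases CHI9 (1.06 ± 0.16 SE) and CHI3 (0.88 ± 0.15 SE). PR-5 moved to 2.12 without wild type replicate 1 and to 4.43 without wild type replicate 2. Without L7 replicate 1 these 6 genes lost their calls, and without L7 replicate 2 all of them but GluB did, PR-5 with an adjusted p of 0.422 and 0.342 in limma. The calls of P4 and NP24-I also ended after median centring (limma adjusted p = 0.0899 and 0.0561), and that of P4 with the dimmest 50% left out (0.0551). The median log2 difference of the list was 1.18 (camera adjusted p = 1.83e-13). It had an adjusted p = 0.145 with an estimated correlation and an adjusted p = 0.0272 in fry. The members of these lists were filled in by symbol after a first fit had been seen, so neither shift is independent evidence of its direction. The actin ratio given above separated the genotypes in the same way as both lists did, whereas the GAPDH and EF1a ratios overlapped. The overlap of GAPDH was narrow, with 2.597 on wild type replicate 1 and 2.605 on L7 replicate 2. With 2 arrays against 2, a single measure separates by chance in 33.3% of cases.

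**Figure D2:**
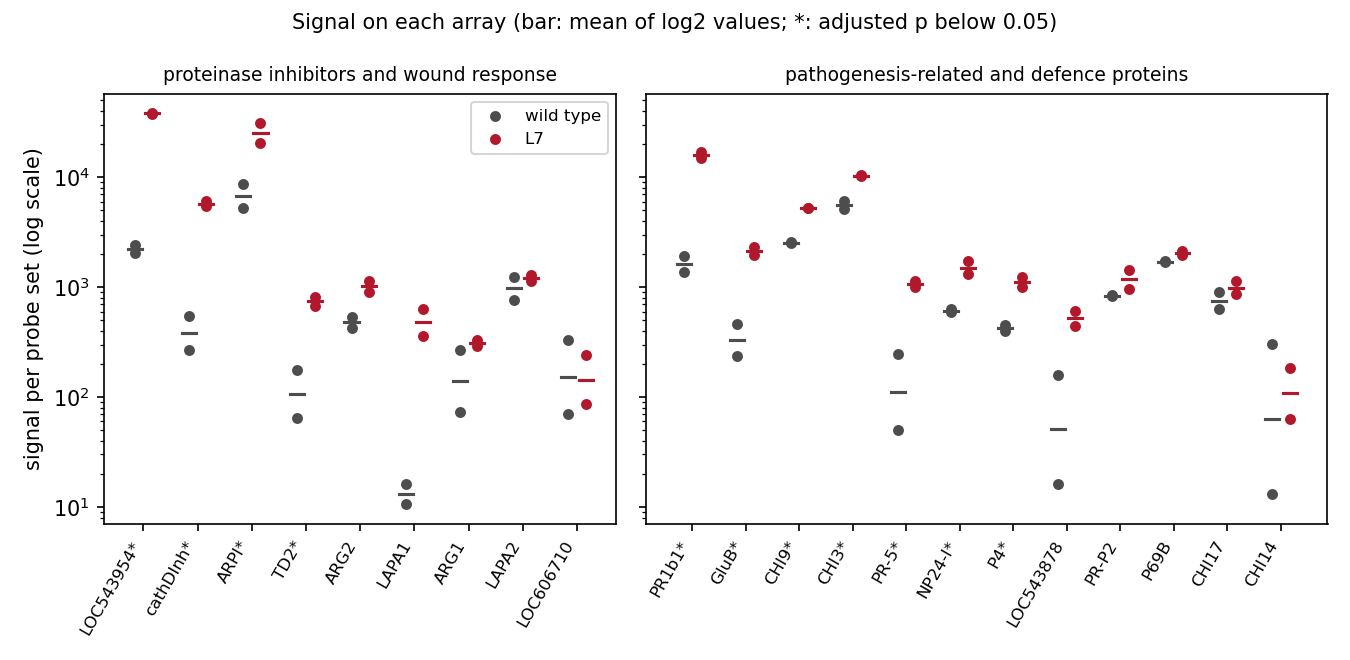
Points are the signals of the 4 arrays on a log axis, grey for wild type and red for L7, for the 9 proteinase inhibitor and wound genes and the 12 pathogenesis-related genes, with bars at the mean of the log2 values. An asterisk marks the 4 and 7 genes with an adjusted p below 0.05, and in each of these both L7 arrays lie above both wild-type arrays.

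Of the 24 lists whose search patterns were written before the data were examined, 13 found no gene, because the annotation holds symbols and no descriptions, and 4 had enough genes to test. The pathogenesis-related pattern found 9 tested genes, of which PR1b1 and PR-5 rose, and shifted upward (median log2 0.57, camera adjusted p = 3.63e-05). Its adjusted p was 0.173 with an estimated correlation and 0.0498 in fry. The pattern also took in genes such as PRO2 and PRK2, which share only letters of the symbol. The light harvesting and photosystem pattern found 8 tested genes, with 0 called over all probe sets and 1 lower when adjusted over the list alone, PSBR, and shifted downward by a median log2 of -0.16 (camera adjusted p = 0.0292). Its 8 genes all had a lower mean in L7, and fry gave an adjusted p of 0.0498. In camera, its adjusted p was 0.286 with an estimated correlation, and its shift was -0.02 after quantile normalization (adjusted p = 0.357). The call also ended after median centring (0.0743), with no filter (0.0513), with the replicate block (0.193) and without the trend (0.141). It held with the dimmest 50% left out (0.0141) and after adding 16 to each signal (0.0429). The median of the list was -0.17 without wild type replicate 1 and -0.14 without wild type replicate 2. Without L7 replicate 1 it was -0.13, and without L7 replicate 2 it was -0.16. The list of photosystem genes filled in by symbol, with 9 genes, had a median of -0.17 and did not pass (camera adjusted p = 0.0699). Its camera adjusted p was 0.0102 against all probe sets, 0.0397 with the dimmest 50% left out and 0.389 after quantile normalization. PSBR, a photosystem subunit, had the lowest p of that list, with a log2 difference of -0.54 (limma adjusted p = 0.0691), which was -0.13 after quantile normalization (limma adjusted p = 0.768). It was the 1 gene that passed over that list alone, and over all probe sets it passed with the dimmest 50% left out (limma adjusted p = 0.0375), with a robust trend (2.43e-06), without wild type replicate 2 (-0.61, 0.0236) and with the block on hybridisation controls. CAB5, a chlorophyll-binding protein, followed at -0.28 (limma adjusted p = 0.670). The abscisic acid pattern, which mostly matched Rab genes, and the auxin, gibberellin and cytokinin pattern did not pass (camera adjusted p = 0.708 and 0.352).

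Besides LOC543809, 5 named genes fell. NRAMP3, a metal transporter, changed by a log2 difference of -1.90 ± 0.46 SE (limma adjusted p = 0.0409) and PPCK1, a kinase of phosphoenolpyruvate carboxylase, by -1.66 ± 0.36 SE (limma adjusted p = 0.0184). LOC544187 (-0.98), LOC544298 (-0.92) and DHAR2, a dehydroascorbate reductase (-0.82, limma adjusted p = 0.0440), also fell. NRAMP3 and DHAR2 passed in 0 of the 4 fits that left out an array and PPCK1 in 1, with -1.13 for PPCK1 without wild type replicate 2 (limma adjusted p = 0.361). All 6 genes that fell, LOC543809 included, lost their calls without L7 replicate 1, with log2 differences then of -2.18 for NRAMP3, -1.76 for PPCK1, -1.13 for LOC543809, -0.90 for LOC544187, -1.28 for LOC544298 and -0.92 for DHAR2. The calls of NRAMP3, LOC544298 and DHAR2 also ended after median centring and with the dimmest 50% left out, that of DHAR2 after quantile normalization as well, and that of PPCK1 with the dimmest 50% left out. Without L7 replicate 2, LOC544298 had a log2 difference of -0.55 (limma adjusted p = 0.714). LOC543809 was the 1 called gene among 13 tested genes of inositol, phospholipid and calcium signalling, and the list did not pass (camera adjusted p = 0.764). DHAR2 was likewise the 1 called gene among 22 antioxidant and ascorbate or glutathione genes (camera adjusted p = 0.764), where the catalase cat1 had a log2 difference of 0.38 (limma adjusted p = 0.284).

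Further genes that rose were pip1 (log2 1.86 ± 0.32 SE), the subtilase sbt3 (1.84 ± 0.43 SE) and, among 36 cell wall genes, 2 called ones: the pectin methylesterase PMEU1 (1.29 ± 0.25 SE) and the xyloglucan endotransglucosylase XTH16 (0.89 ± 0.16 SE). Without L7 replicate 1 these genes lost their calls, and without L7 replicate 2 all but pip1 did. The call of sbt3 also ended after median centring and with the dimmest 50% left out (limma adjusted p = 0.0734 and 0.0551). Adjusted over the cell wall list alone, 4 genes were higher and 2 lower, and the list did not pass (camera adjusted p = 0.695). ACO6, an enzyme of ethylene synthesis, was called on 1 of its 3 probe sets (log2 1.13, limma adjusted p = 0.00228). Its brightest gave 0.46 (limma adjusted p = 0.259) and the remaining one 0.88 (limma adjusted p = 0.186). On each of the 3, both L7 arrays lay above both wild-type arrays. Among the 59 unnamed probe sets, the largest rise was a log2 difference of 4.93 and the largest fall one of -2.90.

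A count that uses no variance model gave a different picture of size. Differences beyond 2-fold in all 4 pairings of an L7 array with a wild-type array were found for 329 probe sets, 186 higher and 143 lower in L7, and after quantile normalization for 328, 165 higher and 163 lower. The other splits of the arrays into pairs gave 280 (replicate 1 against replicate 2) and 296 (1 array of each genotype on either side), so that total did not stand apart from them. In limma's test both of those splits called 0 probe sets, with 137 and 224 at an unadjusted p below 0.05. Each of them has 1 array of each genotype on either side, so that genotype differences add to its spread, and its 0 is no measure of what chance alone would give. With 2 arrays per genotype, the smallest two-sided p of an exact permutation test for a single probe set is 0.333.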

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

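Without the variance trend 0 probe sets passed in place of 86, and 52 passed after median centring. A block on hybridisation controls, chosen after seeing the data, gave 207. Fits without 1 array gave 11 to 124, the lowest without L7 replicate 1, with the lone array assumed to vary like the other genotype's. The replicate number as a block gave 106. The main model had no such block, as fixed beforehand, because the labels give replicate numbers and no shared culture or day. Replicates 1 and 2 did not deviate together across genotypes (correlation 0.0005). With noisy dim probe sets included, that value does not show that samples were unpaired. The remaining settings gave 59 to 108. The count beyond 2-fold in all pairs was 820 with no filter, 77 with the dimmest 50% left out and 911 to 1323 without 1 array, where fewer pairs need to pass. Of the lists fixed beforehand, 1 in place of 2 passed after quantile normalization, after median centring, with no filter, with the replicate block and without the trend, 1 to 2 without 1 array, and 0 with an estimated correlation; the robust fit was not run for lists. Of the lists by symbol, 0 passed with an estimated correlation, 1 in fry, 4 against all probe sets and 2 to 4 without 1 array. The cause of these shifts was not tested. Among the 22 called genes followed, 0 changed direction in any setting, while 18 lost their call without L7 replicate 1, 6 after median centring and 7 with the dimmest 50% left out. Of the 19 uncalled genes followed, 12 gained a call with the block on hybridisation controls, 4 with a robust trend, 3 with the replicate block and 3 to 4 without 1 wild type array. LOC543955, LOC543954, cathDInh and PR1b1 were called in 12 of 13 settings, all but the fit without the trend. The lost calls were not traced to brightness. Low signal limits precision in general: the median spread within genotypes was log2 1.56 in the dimmest 25% of tested probe sets and 0.19 in the brightest.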

Other observations

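The lists by symbol, the comparison with all probe sets, the photosystem test with its bound, the split by brightness and the jasmonate test were chosen after the results were seen. Of 7 tested heat shock and chaperone genes, 0 were called over all probe sets and 3 were lower when adjusted over the list alone: vis1 (log2 -4.07, limma adjusted p = 0.142), CPN21 (-0.52, limma adjusted p = 0.261) and HSP17-6 (-0.91, limma adjusted p = 0.280). Single arrays or a constant moved these values. The log2 difference of vis1 was -3.21 after adding 16 to each signal and -6.41 without L7 replicate 1. It was -1.73 without L7 replicate 2, the array with its lowest signal. CPN21 and HSP17-6 were -0.33 and -0.52 without wild type replicate 2, but -0.71 and -1.30 without wild type replicate 1. Of 11 ribosomal and translation genes, 0 were called and 2 were lower over the list alone. These were rpl38 (-0.72, limma adjusted p = 0.0524) and eIF-5A1 (-0.58, limma adjusted p = 0.126). In limma, rpl38 passed with no filter (0.0458), an added 16 (0.0455), the replicate block (0.0317) and a robust trend (0.0301). It did not after quantile normalization (0.0598), median centring (0.166), with the dimmest 50% left out (0.110) or without the trend (0.855). Of 7 root genes, a list for tissue of which whole seedlings can hold different shares, NRAMP3 fell, TIP had a log2 difference of -2.61 (limma adjusted p = 0.342) and RSI-1 one of -0.70 (limma adjusted p = 0.541). The root list had a median of -0.70 (camera adjusted p = 0.222, or 0.0185 against all probe sets). It rests on single L7 arrays, with a median of -1.52 without L7 replicate 1 (camera adjusted p = 0.0285) and -0.03 without L7 replicate 2 (camera adjusted p = 0.341), and TIP was -1.58 without L7 replicate 1 and -3.63 without L7 replicate 2.

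None of the other lists by symbol passed the list test or held a called gene on its brightest probe set. Their camera adjusted p-values were 0.764 for 17 carotenoid and isoprenoid genes, where the zeaxanthin epoxidase ZEP had a log2 difference of -0.78 (limma adjusted p = 0.215), 0.996 for 8 phenylpropanoid genes, 0.996 for 22 ethylene genes, 0.491 for 12 AP2/ERF genes and 0.996 for 9 abscisic acid genes. They were 0.583 for 13 auxin, gibberellin and brassinosteroid genes, 0.996 for 21 sucrose and starch genes, 0.315 for the ribosomal list, 0.301 for the heat shock list, 0.996 for 11 photoreceptor genes, 0.996 for 11 cell cycle genes and 0.939 for 9 fruit and floral genes. The phosphate list had 3 tested genes and was not tested.

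The first pattern weighed is that wound and pathogenesis-related genes were higher in L7, with a median log2 difference of 1.30 over the 21 tested, called or not. Hybridisation controls were brightest on 1 array of each genotype, and the median was 1.44 within that pair and 1.85 within the other pair. A larger share of green shoot in L7 would raise photosystem genes as well, yet their median was -0.171. Upper bounds from resampling the 9 genes were -0.06 as deposited, 0.03 after quantile normalization and -0.09 after median centring. All were under 0.65, the rise set as the bound after the results were seen. For these arrays, that argues against a larger green share as the whole cause, provided that green tissue held equal photosystem transcripts in both genotypes. Whether it did was not measured. Resampling genes carries no spread between arrays or seedlings, and tissue shares were not measured. The root list did not pass and its median of -0.70 became -0.03 without L7 replicate 2, so it decides nothing here. An effect of the transgene, of the insertion site or of RNA integrity stays open and untested. Of the RNA ratios, that of actin separated the genotypes and that of GAPDH overlapped only narrowly. The hypothesis that the transgenic line has raised defence transcripts thus may hold but is not established by 2 arrays per genotype.

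The second pattern is that the 2-fold count in all pairs was nearly as high for other splits of the arrays. In the dimmest 25% of tested probe sets the genotype split counted 231, against 230 for the replicate split and 223 for the split by hybridisation controls, while in the brightest 25% it counted 25 against 0 and 1, a ratio of 25 to the higher of the other splits. This is consistent with noise of dim probe sets filling most of the 329.

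The third pattern is that wound genes rose while none of 12 jasmonate and oxylipin genes was called. A candidate explanation of the rise is a higher level of jasmonate synthesis and signalling transcripts. The list tested mixes both with oxylipin genes, so it cannot single out synthesis, and it did not pass (camera adjusted p = 0.996). Its members went both ways: 5 of the 12 had a higher mean in L7, and the median log2 difference was -0.06. Adjusted over the list alone, MYC2 (log2 0.88, limma adjusted p = 0.174) and HPL (0.80, limma adjusted p = 0.177) were higher and 0 genes lower. Hormone levels were not measured, and a p that misses the threshold leaves this explanation open.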
